A study of Mus musculus with 6 samples.

How the data were processed

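RNA from colon tissue of 3-week-old C57BL/6J mouse offspring was measured in 6 libraries. The 3 control libraries came from offspring of dams given 0% dextran sulfate sodium (DSS), and the 3 maternal DSS libraries from offspring of dams given 1.5% DSS. DSS is a sulfated polysaccharide that damages the colon lining and is used to induce colitis in mice. The sample labels give the exposure of the dams as embryonic day 13 to 19, and the series design text gives it as 5 days in the second trimester. The labels speak of offspring in the plural for each library, so a library may hold RNA of 1 animal or of a pool. The labels name no litter, dam, sex or batch. The p-values of single genes therefore measure the spread between these libraries, part of which may come from handling. The DSS was given to dams, so libraries from 1 dam could spread less than libraries from separate dams. If the libraries of a group share a dam, effects of the dam and of DSS cannot be told apart.

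Total RNA was purified with a lipid tissue kit and made into stranded mRNA libraries, per the labels' protocols. The values analysed here are FPKM (fragment counts scaled by transcript length and by the library total) per gene and library, as deposited by the authors. The submitters' processing notes name FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0, StringTie 2.1.3b, DESeq2 without a version, and the mm10 genome build, with no role or order. Which of these made the FPKM values, and with which annotation, is not given in the sources used here. The table has 20594 genes, each once by symbol with RefSeq transcript identifiers, and all 6 of its sample columns were used. A 0 stands in only 2 of the 20594 rows, so the table appears to hold genes with signal in nearly every library.

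Read counts were not analysed here. The low FPKM values do not fall on steps of whole reads, so the depth of the libraries is unknown and no counting interval is given. FPKM divides by a library's own total and by transcript length. A library whose reads favour short or long transcripts, or in which a few RNAs take many reads, is therefore shifted across many genes at once. The FPKM sums per library ranged from 403673 to 492719. Of the 20594 symbols, 19959 (96.9%) matched the RefSeq gene table of GRCm38.p6, the assembly that mm10 names, and coordinates come from it. Transcript lengths were the longest transcript per symbol in GENCODE M21, and 13204 of the 13594 tested genes (97.1%) had one.

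The design chosen before the data were examined assumed read counts and named a test for a table of FPKM alone, which was used. Genes with an FPKM of at least 1 in at least 3 libraries were kept (13594 genes). Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, for group alone. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are maternal DSS minus control on the log2(FPKM + 1) scale, which understates the change of low genes. A looser count took genes with at least a 2-fold change and an unadjusted p under 0.05. In data simulated with the spread that limma estimated and no structure between libraries, for the comparison of maternal DSS with control over 13594 genes, the fit recovered 24 of 50 genes changed 1.5-fold, 39 of 50 changed 2-fold, 46 of 50 changed 4-fold and 50 of 50 changed 8-fold, with 8 false calls. The real libraries do have structure between them, so this recovery does not carry over. An absence of calls in them does not exclude changes of these sizes.

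Before the data were examined, 48 gene lists of pathways, cell types and gut regions were written. The 43 with at least 5 tested genes were tested with limma's camera (two-sided, preset inter-gene correlation 0.01), adjusted over the 43. The other 5 (dendritic cells, mast cells and eosinophils, neutrophils, pancreatic acinar cells and red blood cells) had fewer tested genes and were not tested in the main fit. Settings that kept more genes also tested lists from these 5, with 48 lists tested without a filter and 47 after TPM scaling. The design named camera on a count fit, and it was run on the log2 FPKM matrix instead. Camera with an estimated correlation and the fry test were run beside it. For simulated lists of 20 genes, camera called the 1 list shifted by 0.5 on the log2 scale and none of the other 40. That simulation gave genes no correlation, so it does not test the preset. With the preset, camera p-values rest mainly on the spread across genes, and little on that between libraries. Splits of the 6 libraries into 3 against 3 other than the real one gave 10 to 25 called lists with the preset. A list score per library is the mean of log2(FPKM + 1) over tested genes minus the control mean, compared by a two-sided exact permutation test whose smallest possible p with 3 against 3 libraries is 0.1.

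Genes were named by a rule fixed before the data were examined. It takes up to 12 genes per direction in which all libraries of one group lie above all of the other, with a mean of at least 1 in the higher group and no predicted-gene symbol. Genes passing the adjusted threshold come first and the rest are filled by smallest p, with at most 2 immunoglobulin or T cell receptor segments. It also takes up to 4 genes of each called list by smallest p, and 14 genes set in advance (Muc2, Reg3g, Reg3b, Tjp1, Ocln, Cldn2, Lgr5, Mki67, Il1b, Tnf, Lcn2, Igha, Hoxb13 and Xist). The rule's minimum was stated in CPM and was applied to FPKM. Other genes named in the text were chosen after their values were seen, and each part says so. Single values of 2 genes that the rule takes are not reported here; both stay in the list tests.

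Alternatives chosen before the data were examined were a pseudocount of 0.1, no expression filter, the replicate number as a block, a sex term, and leaving out each library. Chosen after the data were seen were median-ratio scaling, TPM scaling of the listed genes, array weights, a filter at an FPKM of 5, removal of each library's trend with transcript length (lowess, span 0.3), and the first component of the residuals as a term. A further list of 32 small intestine genes, 30 of them in the table, was also written after the data were seen, and it replaced an earlier test on the list that had shown the pattern. The length test of Fkbp5, Zbtb16, Mt1 and Mt2 replaced an earlier one that counted how many kept the groups apart, which their selection had largely fixed. Their selection by small p also largely fixed the lower limit in the newer test, so only the shift in fold change is read.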

Results

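The study asked how colitis in the pregnant dam relates to the intestine of the offspring. The data are FPKM values of 20594 genes in colon from 3-week-old offspring, with 3 control libraries and 3 maternal DSS libraries. Libraries are named by group and replicate number. Their depth is unknown, and between 13249 and 13739 genes per library reached an FPKM of 1.

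No gene passed the adjusted threshold between maternal DSS and control offspring. Targets of the glucocorticoid receptor and metallothioneins (Fkbp5, Zbtb16, Mt1, Mt2), the immunoglobulin segments Ighv1-18 and Ighj3, and the goblet cell product Retnlb were higher in all 3 maternal DSS libraries than in all 3 controls. The inducible heat shock genes Hspa1a and Hspa1b, the secretory lineage factor Atoh1, the NF-kB regulators Tnfaip3 and Bcl3, and the desaturase gene Scd2 were lower in all 3. In limma, 0 of 13594 genes had an adjusted p under 0.05 (smallest adjusted p = 0.49), and 1064 had an unadjusted p under 0.05, of which 329 were higher and 735 lower. With at least a 2-fold change and an unadjusted p under 0.05 there were 23 genes, 21 higher and 2 lower. The groups did not overlap in 1912 genes (14.1%), 669 higher and 1243 lower. Over the 10 possible splits of the libraries into 3 against 3 this share averages 10%. Genes vary together, so a single split can lie far from that average, and the difference was not tested.

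These counts depended on single libraries and on the scaling. The 23 genes with a 2-fold change became 86 without maternal DSS 1, 45 without control 3 and 14 without maternal DSS 3. The 1064 genes became 3368 without maternal DSS 1, 489 without control 1, 401 without control 2, 628 without maternal DSS 2 and 631 without maternal DSS 3. The share of higher genes among the 1064 was 30.9%, against 48.3% after median-ratio scaling, 10.5% after TPM scaling and 48% with the transcript-length trend removed. TPM scaling moved the median log2 fold change of all genes from -0.037 to -0.139, so small differences in level are read relative to that median. Limma with array weights called 4933 genes, giving maternal DSS 2 a weight of 5.47 and maternal DSS 1 one of 0.249.

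Among the genes higher in maternal DSS offspring, Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28398753 to 28486149), had 46.4 ± 2.79 FPKM against 24.6 ± 7.05 in controls (SD, n = 3 each; log2 fold change 0.92, SE 0.18, adjusted p = 0.61 in limma). Zbtb16, a transcription factor gene induced by glucocorticoids (chromosome 9, 48651797 to 48836225), had 3.3 ± 0.597 against 0.832 ± 0.708 FPKM (log2 fold change 1.29, SE 0.25). The metal-binding Mt1 (chromosome 8, 94178883 to 94180327) had 261 ± 21 against 160 ± 17.5 FPKM (log2 fold change 0.70, SE 0.11, adjusted p = 0.49), and its neighbour Mt2 had 170 ± 37.7 against 87.7 ± 17.4. The stress-responsive Nupr1 had 305 ± 27.5 against 198 ± 9.65 FPKM, Ubald2 had 49.8 ± 4.33 against 34.1 ± 3.37, and Glycam1 had 4.9 ± 1.59 against 1.29 ± 0.408. The mitochondrial tRNA genes TrnT and TrnP had log2 fold changes of 1.05 and 0.93. The cytoplasmic 7S RNA copies Rn7s1 and Rn7s2 both had 0.84, and since they are near-identical they count as one uncertain signal. TrnT, TrnP, Rn7s1 and Rn7s2 are short transcripts, which an mRNA kit captures poorly.

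**Figure D1:**
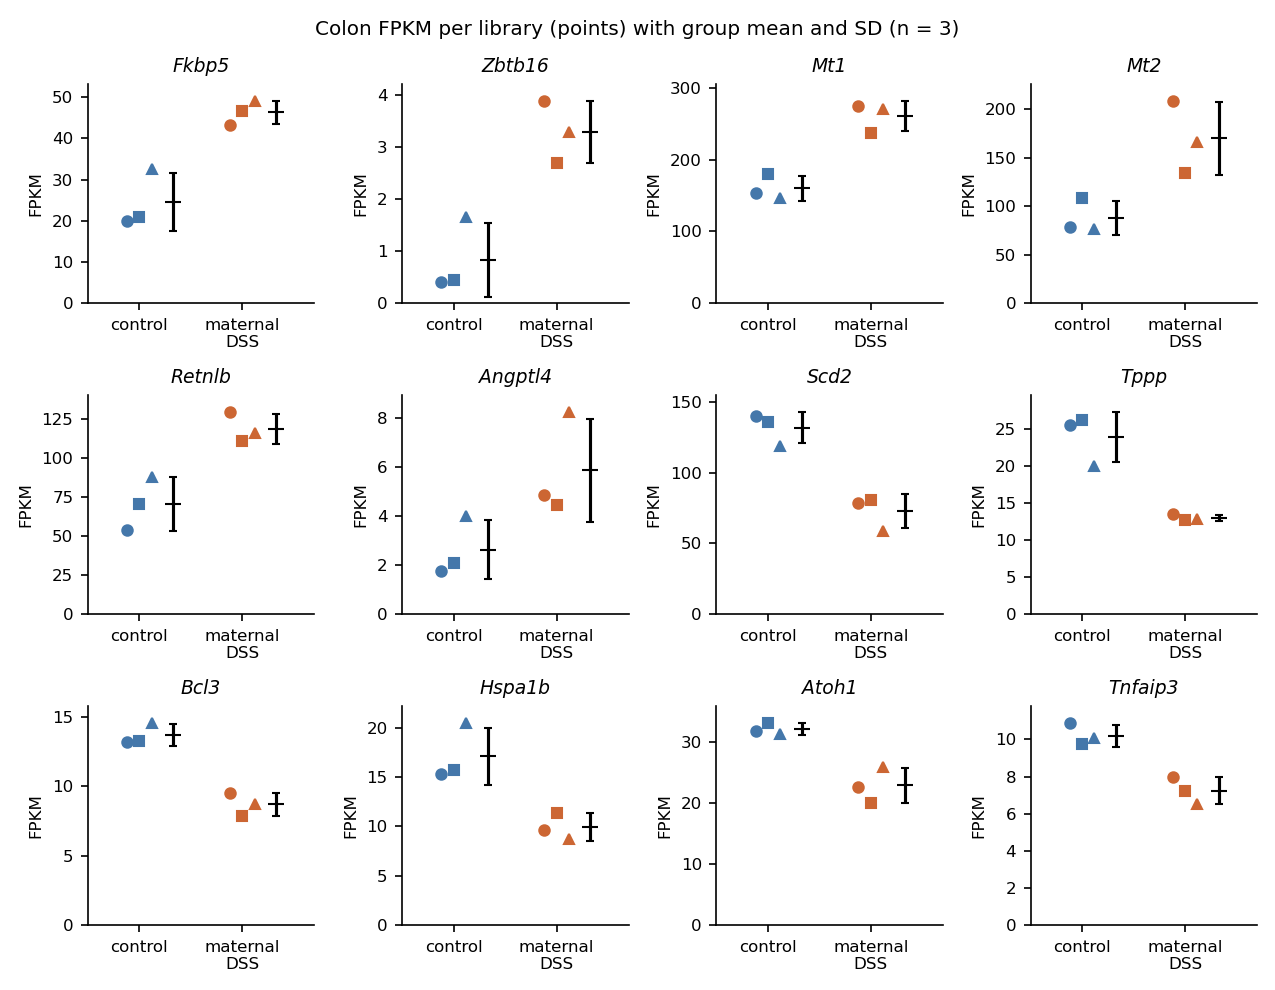
FPKM of 12 genes in each colon library. Circles, squares and triangles are replicates 1, 2 and 3 of control (blue) and maternal DSS (orange), with the group mean and SD beside them (n = 3). In each panel the 3 libraries of one group lie above the 3 of the other, and none of the 12 genes passed the adjusted threshold in limma.

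The glucocorticoid response list was called higher by camera (adjusted p = 0.0038), but adjusted p = 0.44 with an estimated correlation. Of its 13 tested genes 7 were higher and 6 lower. None passed over all genes, and 4 passed adjusted over the list alone: Mt1, Fkbp5, Zbtb16 and Mt2. Its score was 0.29 ± 0.13 in maternal DSS against 0 ± 0.17 in control libraries (SD, exact permutation p = 0.2). Other glucocorticoid targets, picked after their values were seen, had smaller differences. Klf9 had a log2 fold change of 0.15 (SE 0.09), Tsc22d3 0.09 (SE 0.29), Sgk1 -0.10 (SE 0.32), Per1 -0.01 (SE 0.17) and Dusp1 -0.07 (SE 0.11). The call of the list ended at the stricter filter of an FPKM of 5 (adjusted p = 0.064).

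Among the genes lower in maternal DSS offspring, Tppp, a tubulin polymerisation gene (chromosome 13, 74009419 to 74035753), had 13 ± 0.44 against 24 ± 3.39 FPKM (SD, n = 3 each; log2 fold change -0.83, SE 0.11, adjusted p = 0.49 in limma). Scd2, a fatty acid desaturase gene (chromosome 19, 44293676 to 44306864), had 72.7 ± 12 against 132 ± 11.2 FPKM (log2 fold change -0.86, SE 0.14, adjusted p = 0.49). Bcl3, an IkB family gene, had 8.72 ± 0.822 against 13.7 ± 0.804 FPKM, and Tnfaip3, which encodes the NF-kB inhibitor A20, had 7.24 ± 0.729 against 10.2 ± 0.585. Atoh1, the factor that commits intestinal progenitors to secretory fates, had 22.9 ± 2.93 against 32.2 ± 0.94, and the endoderm factor Foxa2 had 6.27 ± 0.304 against 8.56 ± 0.346. Caskin2, Rnf145, C2cd4b and Pmepa1 had log2 fold changes of -0.46, -0.39, -0.56 and -0.36.

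The heat shock list was called lower (adjusted p = 0.004 with camera; adjusted p = 0.44 with an estimated correlation), with 12 of 13 tested genes lower. Hspa1b had 9.92 ± 1.41 against 17.1 ± 2.87 FPKM and Hspa1a 6.57 ± 0.949 against 11.4 ± 1.97 (SD, n = 3 each). They are near-identical neighbours on chromosome 17 whose reads cannot be fully told apart. Chordc1 and Dnajb1 had log2 fold changes of -0.39 (SE 0.11) and -0.27 (SE 0.08). None of the 13 passed over all genes and 5 passed adjusted over the list alone. The list score was lower in all 3 maternal DSS libraries (-0.24 ± 0.08 against 0 ± 0.12, exact permutation p = 0.1, the smallest possible). The camera call ended without control 3 (adjusted p = 0.082), without maternal DSS 1 (adjusted p = 0.1) and with array weights (adjusted p = 0.64).

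Lists of energy metabolism were higher in the maternal DSS libraries by small amounts. Of 33 oxidative phosphorylation genes 31 were higher, with a median log2 fold change of 0.13 (camera adjusted p = 9e-09; adjusted p = 0.44 with an estimated correlation). Among them Ndufs3, a subunit of respiratory complex I, had 69.2 ± 2.4 against 60.4 ± 0.836 FPKM, and Ndufa9, Ndufv1 and Cox4i1 had log2 fold changes of 0.26, 0.18 and 0.24. The score was 0.16 and 0.23 in maternal DSS 2 and 3 and 0.03 in maternal DSS 1, below the 0.06 of control 3 (exact permutation p = 0.2). Of 21 fatty acid oxidation genes 19 were higher (camera adjusted p = 3.1e-06; adjusted p = 0.44 with an estimated correlation), 2 of them passing adjusted over the list alone. Acaa2, a mitochondrial thiolase gene, had 81.4 ± 6.49 against 64 ± 1.58 FPKM, and Acot1, Acot2 and the PPAR target Angptl4 had log2 fold changes of 0.43, 0.31 and 0.93. The score of this list was higher in all 3 maternal DSS libraries (0.17 ± 0.12 against 0 ± 0.01, exact permutation p = 0.1). It was 0.27, 0.04 and 0.2 in maternal DSS 1, 2 and 3 and at most 0.01 in controls, so maternal DSS 2 was only just above them. The median transcript of the oxidative phosphorylation list is 1661 nt long. With the length trend removed its camera adjusted p was 7e-05.

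Smaller metabolic lists were also called higher. The ketogenesis and short-chain fatty acid list had 10 of 14 genes higher (camera adjusted p = 0.028; adjusted p = 0.58 with an estimated correlation), with log2 fold changes of 0.44 for the carnitine carrier Slc25a20, 0.08 for Echs1 and 0.12 for Acads. Echs1 had -0.03 after TPM scaling. The glycolysis and hypoxia list had 17 of 23 higher (camera adjusted p = 0.028; adjusted p = 0.44 with an estimated correlation), with Pgk1 at 0.18 and Slc2a1 at 0.13, whereas Hk2 had -0.24 and Adm -0.24. The call of the first ended without control 3 (adjusted p = 0.25), maternal DSS 1 (0.078) or maternal DSS 3 (0.089), and that of the second without control 2 (adjusted p = 0.17), maternal DSS 1 (0.054) or maternal DSS 2 (0.079). Both calls ended after TPM scaling (adjusted p = 0.14 and 0.18).

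Lists of genes that handle bile acids and foreign compounds were called higher. Of 11 bile acid and FXR genes 10 were higher (camera adjusted p = 0.00075; adjusted p = 0.44 with an estimated correlation). The bile acid transporter gene Slc10a2 had 59.6 ± 10 against 40 ± 9.47 FPKM, the exporter subunit Slc51a 58.5 ± 15.6 against 39.4 ± 11.1, and the receptor genes Nr1h4 and Nr1i2 had log2 fold changes of 0.36 and 0.20. The score was 0.63 and 0.42 in maternal DSS 2 and 3, which carried the small-intestinal transcripts, and 0.06 in maternal DSS 1, below the 0.13 of controls 1 and 3 (exact permutation p = 0.3). Of 19 xenobiotic metabolism genes 15 were higher (camera adjusted p = 0.0026; adjusted p = 0.58 with an estimated correlation), with Cyp3a13 at 65 ± 5.39 against 51.3 ± 4.25 FPKM and Ugt1a1, Ces1d and Sult1a1 at log2 fold changes of 0.43, 0.45 and 0.32. Its score was 0.17, -0.04 and 0.23 in maternal DSS 1, 2 and 3 against -0.08 to 0.11 in controls (exact permutation p = 0.3), and its call ended with array weights (adjusted p = 0.38).

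Transcripts of the small intestine list were high in maternal DSS 2 and 3, while maternal DSS 1 scored within the range of the controls. All 13 tested genes of the small intestine and Paneth cell list had positive fold changes (camera adjusted p = 2.4e-06; adjusted p = 0.44 with an estimated correlation), but the list score was -0.13, 1.28 and 1.42 in maternal DSS 1, 2 and 3. The lectin gene Itln1 had 0.997, 7.3 and 11.4 FPKM in the 3 maternal DSS libraries against 0.952 ± 0.687 in controls (SD, n = 3). Mmp7, a Paneth cell protease gene, had 1.05, 3.13 and 3.44 against 0.887 ± 0.419, and Ada 3.19, 5.37 and 5.69 against 3.29 ± 0.51.

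The antimicrobial list had 17 of 19 genes higher (camera adjusted p = 0.00013; adjusted p = 0.58 with an estimated correlation). The list score was -0.27, -0.36 and 0.64 in controls 1, 2 and 3 and -0.14, 0.97 and 0.93 in maternal DSS 1, 2 and 3 (exact permutation p = 0.2). Itln1 and Lyz1 are in both this list and the small intestine list. Retnlb, which encodes a goblet cell protein that acts on bacteria, had 119 ± 9.76 against 70.8 ± 17.3 FPKM (SD, n = 3 each; log2 fold change 0.77, SE 0.17, adjusted p = 0.62 in limma) and was the antimicrobial list's 1 gene to pass adjusted over the list alone. It also passed in the type 2 immunity list, which was not called (adjusted p = 0.39). The lysozyme gene Lyz1 had 2.19, 16.7 and 28.5 FPKM in maternal DSS 1, 2 and 3 against 3.41 ± 1.54 in controls, and Slpi a log2 fold change of 0.39. Reg3b, an antibacterial lectin gene, had 146, 60.7 and 1730 FPKM in controls 1, 2 and 3 and 291, 2120 and 2280 in maternal DSS 1, 2 and 3. Reg3g had 56.8, 19 and 145 against 46.9, 332 and 382, so control 3 was high for both.

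Of 47 tested genes with immunoglobulin or T cell receptor symbols, constant regions included, 45 were higher (median log2 fold change 0.86). In 13 of them all maternal DSS libraries lay above all controls. The genes were picked by symbol alone, so an unrelated gene with a like symbol, such as Tradd, may be counted. Ighv1-18 had 2.99 ± 1.06 against 0.313 ± 0.146 FPKM (SD, n = 3 each) and Ighj3 8.93 ± 3.8 against 1.47 ± 0.509, with log2 fold changes of 1.58 and 1.95 and an adjusted p = 0.49 for both in limma. Segments of one family share reads, so their single values are uncertain. Igha, the constant region of the mucosal antibody IgA, had 51.2, 228 and 342 FPKM in maternal DSS 1, 2 and 3 against 37.2 ± 5.66 in controls. Igkc had 87.1, 456 and 628 against 61.8 ± 17.2, and Jchain, which joins IgA units, 6.88, 44.7 and 62.6 against 6.9 ± 1.13. In maternal DSS 1, Igha and Igkc lay above all 3 controls (at most 42.6 and 81.6) and Jchain within their range. Prdm1, a plasma cell factor that is also in the weaning list, had a log2 fold change of 0.41 (SE 0.12) and its highest value in maternal DSS 1 (2.42 FPKM). The B and plasma cell list had 7 of 10 genes higher (camera adjusted p = 0.004; adjusted p = 0.58 with an estimated correlation), of which 3 passed adjusted over the list alone. Its call ended without maternal DSS 2 (adjusted p = 0.14). Without maternal DSS 1, limma called 12 genes, all higher, with adjusted p from 0.0059 to 0.047: Jchain, Igha, Igkc, Ighj4, Ighj3, Igkv14-111, Ighv1-18, Igkj4, Lgals2, Anpep, Ccl25 and Clca4b.

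**Figure D2:**
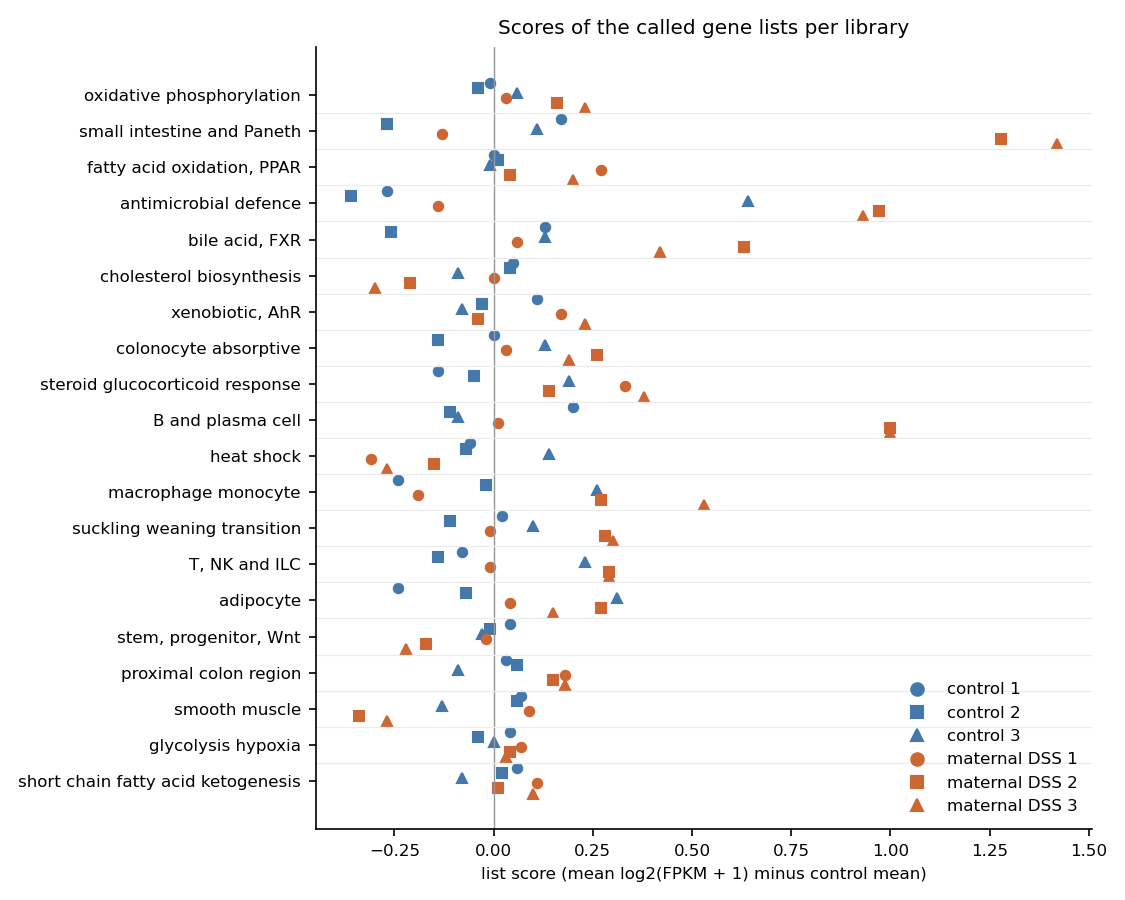
Scores of the 20 called gene lists in each library, as mean log2(FPKM + 1) minus the control mean on the horizontal axis. Points are single libraries (blue control, orange maternal DSS). For the small intestine and Paneth cell list maternal DSS 2 and 3 score 1.28 and 1.42 and maternal DSS 1 scores -0.13.

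Lists of gut region and absorptive cells were called higher. The absorptive colonocyte list had 18 of 22 genes higher (camera adjusted p = 0.0033; adjusted p = 0.44 with an estimated correlation), including Krt20 (495 ± 8.05 against 423 ± 22.6 FPKM), Fabp2 (423 ± 65 against 318 ± 66.3) and the sodium exchanger Slc9a3 (43.8 ± 9.85 against 28.2 ± 11.2), while the sodium channel subunit Scnn1a had a log2 fold change of -0.25. The proximal colon list had 9 of 16 higher, with a median of 0.03 and a mean of 0.17 (camera adjusted p = 0.024; adjusted p = 0.44 with an estimated correlation). Its 2 genes passing adjusted over the list alone were Retnlb and Slc37a2 (63.5 ± 5.53 against 44.3 ± 7.86 FPKM), and Mptx2 had a log2 fold change of 0.73. The proximal colon score was higher in all 3 maternal DSS libraries (0.17 ± 0.02 against 0 ± 0.08, exact permutation p = 0.1). The weaning transition list had 15 of 18 higher (camera adjusted p = 0.0053; adjusted p = 0.44 with an estimated correlation). Within this list Ass1 and Dab2 had log2 fold changes of -0.22 and -0.23, Prdm1 0.41 and Arg2 0.30. Its named genes thus went both ways, and the call gives no direction of development. The weaning score was 0.28 and 0.30 in maternal DSS 2 and 3, which carried the small-intestinal transcripts, and -0.01 in maternal DSS 1, within the controls (-0.11 to 0.10, exact permutation p = 0.3). The colonocyte score was likewise 0.26 and 0.19 against 0.03 in maternal DSS 1, below the 0.13 of control 3 (exact permutation p = 0.2). The colonocyte call ended without maternal DSS 2 (adjusted p = 0.073), and the proximal colon call without control 3 (adjusted p = 0.082), after median-ratio scaling (0.051) and with the length trend removed (0.089).

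Macrophage, T cell and adipocyte lists were called higher, but control 3 scored about as high on them as maternal DSS 2. The macrophage list had 16 of 18 genes higher and none with an unadjusted p under 0.05 (camera adjusted p = 0.004; adjusted p = 0.66 with an estimated correlation). Its score was -0.24, -0.02 and 0.26 in controls 1, 2 and 3 and -0.19, 0.27 and 0.53 in maternal DSS 1, 2 and 3 (exact permutation p = 0.4). Ms4a7, Ly6c2 and Ccr2 had log2 fold changes of 0.43, 0.60 and 0.21, and Cx3cr1 -0.21. The T, NK and innate lymphoid cell list had 8 of 10 higher (camera adjusted p = 0.014; adjusted p = 0.58 with an estimated correlation), with Trbc2 at 0.40, Cd3g at 0.39, Gzma at 0.45 and Cd4 at 0.15. Its score was 0.23 in control 3, -0.01 in maternal DSS 1 and 0.29 in both others of that group (exact permutation p = 0.2). The adipocyte list had 10 of 12 higher (camera adjusted p = 0.019; adjusted p = 0.58 with an estimated correlation), with Fabp4 at 0.32, Cidec at 0.22, Car3 at 0.22 and Pparg at 0.17, and its highest score was that of control 3 (0.31, against 0.04, 0.27 and 0.15 in maternal DSS 1, 2 and 3; exact permutation p = 0.5). The macrophage call ended without control 1 (adjusted p = 0.27), maternal DSS 2 (0.051) or maternal DSS 3 (0.31). The T cell call ended without control 1 (adjusted p = 0.055), control 2 (0.083), maternal DSS 2 (0.051) or maternal DSS 3 (0.087), and with the length trend removed (0.15). The adipocyte call ended without control 1 (adjusted p = 0.22) or maternal DSS 2 (0.073), after median-ratio scaling (0.051), with the length trend removed (0.13) and without an expression filter (0.081).

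The other 3 lists called lower were cholesterol synthesis, stem and Wnt genes, and smooth muscle. Of 23 cholesterol synthesis genes 21 were lower (camera adjusted p = 0.00095; adjusted p = 0.60 with an estimated correlation). Mvd had 11.8 ± 1.06 against 14.9 ± 0.527 FPKM, and Dhcr7 and the rate-controlling Sqle had log2 fold changes of -0.26 and -0.27. Of 18 stem and Wnt genes 15 were lower (camera adjusted p = 0.022; adjusted p = 0.60 with an estimated correlation). Sox9 had 7.8 ± 0.437 against 10.2 ± 0.808 FPKM and the stem cell factor Ascl2 1.12 ± 0.188 against 1.89 ± 0.342. The Wnt feedback genes Nkd1 and Znrf3 had -0.33 and -0.24, while Lgr5 had 2.39 ± 0.655 against 2.54 ± 0.421. Of 18 smooth muscle genes 17 were lower (camera adjusted p = 0.025; adjusted p = 0.69 with an estimated correlation), with Smtn, Lmod1, Synm and Kcnmb1 at -0.32, -0.26, -0.47 and -0.21. Maternal DSS 1 scored 0, -0.02 and 0.09 on these 3 lists, above control 3 at -0.09, -0.03 and -0.13, so the lower scores were those of maternal DSS 2 and 3. The stem call ended without control 3 (adjusted p = 0.065) or maternal DSS 3 (0.18), after TPM scaling (0.15) and with the length trend removed (0.071). The smooth muscle call ended without control 1 (adjusted p = 0.056) or maternal DSS 2 (0.36).

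Lists of barrier, mucus and inflammation genes did not pass the test. The goblet cell and mucus list was not called (camera adjusted p = 0.29, 13 of 20 genes lower). Its 1 gene passing adjusted over the list alone was Atoh1. Muc2, the main mucin, had 699 ± 264 against 726 ± 93.1 FPKM (SD, n = 3 each; log2 fold change -0.11, SE 0.25, adjusted p = 0.88 in limma). The tight junction list was not called (adjusted p = 0.64, 19 of 24 lower), with Tjp1 at 19.8 ± 4.8 against 23.2 ± 3.15 FPKM, Ocln at 24.6 ± 1.13 against 26.3 ± 3.65 and Cldn2 at 52.6 ± 7.21 against 61.9 ± 11.6. The cytokine and chemokine list had an adjusted p of 0.95 and the interferon list one of 0.81. Il1b (0.384 ± 0.215 against 0.293 ± 0.156 FPKM) and Tnf (0.337 ± 0.109 against 0.382 ± 0.192) were below the filter and not tested, and Lcn2 had 2.38 ± 0.538 against 3.3 ± 3. The TLR and NF-kB list was not called (adjusted p = 0.34), although its score was lower in all 3 maternal DSS libraries (-0.06 ± 0.04 against 0 ± 0.01, exact permutation p = 0.1). Tnfaip3 was its 1 gene passing adjusted over the list alone. The proliferation list (adjusted p = 0.39) held Mki67 at 16.4 ± 5.18 against 19.3 ± 3.23 FPKM, and the distal colon list (adjusted p = 0.83) held Hoxb13 at 79.4 ± 31.5 against 83.4 ± 17.5.

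The remaining lists had camera adjusted p of 0.066 for MHC class II, 0.069 for enteric neurons and glia, 0.069 for circadian genes, 0.07 for fibroblast matrix, 0.1 for apoptosis and 0.1 for MHC class I. The values were 0.17 for immediate early genes, 0.24 for enteroendocrine cells, 0.28 for mesothelium, 0.46 for endothelium and 0.52 for skeletal muscle. They were 0.64 for the NRF2 response, 0.83 for squamous epithelium, 0.83 for tuft cells and 0.94 for the unfolded protein response. Some were called when 1 library was left out: fibroblast matrix lower without control 1 (5.3e-05) or maternal DSS 1 (0.0043), MHC class II and class I higher without control 3 (0.00052 and 0.0012) or maternal DSS 1 (0.0056 and 0.0032), and apoptosis higher without the same 2 libraries (0.048 and 0.0028). Circadian genes were called lower without control 1 (0.034), control 2 (0.033) or maternal DSS 1 (0.021), enteric neurons and glia lower without control 2 (0.021) or maternal DSS 3 (0.03), immediate early genes lower without control 3 (0.048), endothelium lower without control 1 (0.0092) and enteroendocrine cells higher without maternal DSS 1 (0.0063).

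The largest difference among the libraries did not follow the groups. The first principal component held 57.7% of the variance and placed control 3 (7.5), maternal DSS 2 (18.2) and maternal DSS 3 (26.7) opposite control 1 (-14.4), control 2 (-17.2) and maternal DSS 1 (-20.8). Xist, the RNA of the inactive X chromosome, had 30.6 FPKM in control 3, 28.1 in maternal DSS 2 and at most 0.562 in the other 4, and the Y-linked Ddx3y had the opposite pattern (0.0547 and 0.0687 against at least 8.88). Control 3 and maternal DSS 2 were thus read as female and the other 4 libraries as male. These values argue against pools of mixed sex, while a single animal or a pool of a single sex per library stays possible. Across the 13204 genes with a known length, which are not independent replicates, the group log2 fold change fell with transcript length (Spearman's rho -0.49) and so did the first component (rho -0.57). The median log2 fold change went from 0.092 in the shortest of 8 length classes to -0.168 in the longest.

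**Figure D3:**
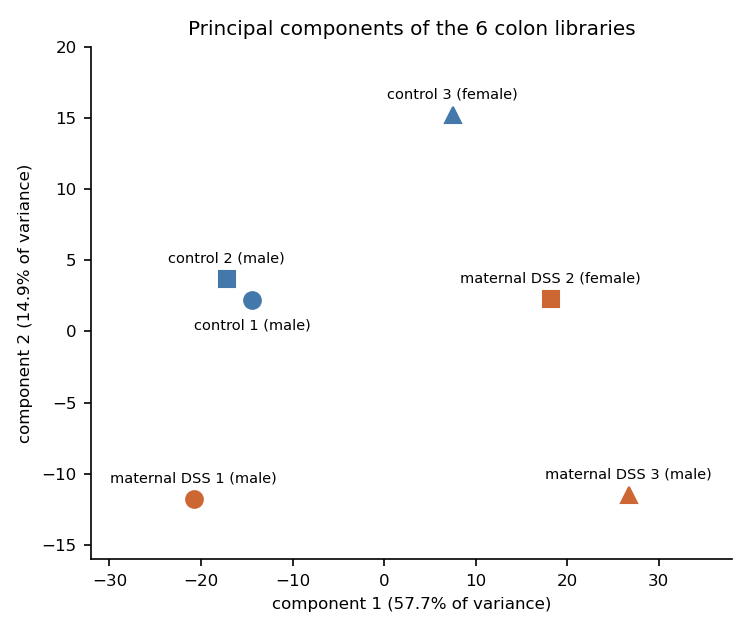
Scores of the 6 colon libraries on the first (57.7% of variance) and second (14.9%) principal components of log2(FPKM + 1) over the 13594 tested genes, with the sex read from Xist and Ddx3y. Control 3 lies on the side of maternal DSS 2 and 3, and maternal DSS 1 on the side of controls 1 and 2.

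**Figure D4:**
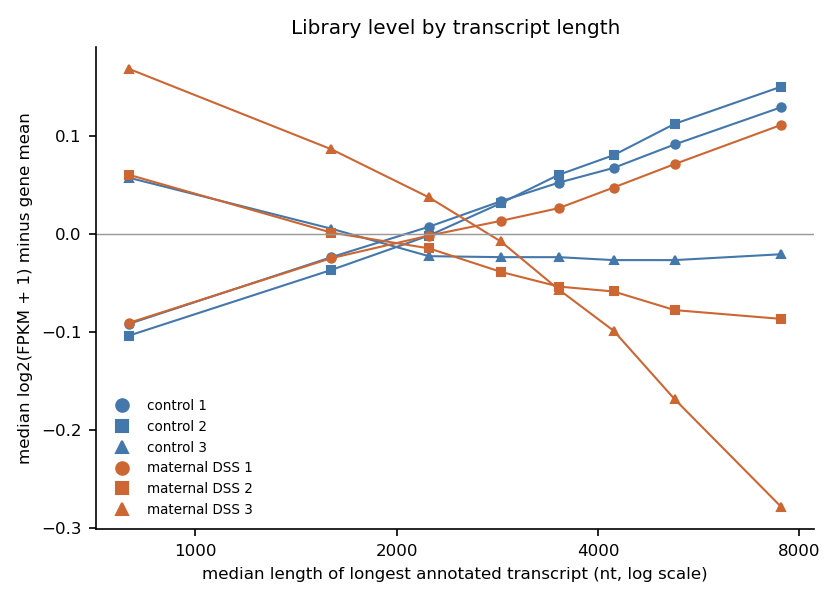
Median deviation of each library from the gene mean of log2(FPKM + 1), in 8 classes of transcript length (horizontal log axis, nt). In the longest class the deviation is 0.15 in control 2 and -0.279 in maternal DSS 3.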

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

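Median-ratio and TPM scaling, array weights, the filter at an FPKM of 5, removal of the length trend and the residual component were chosen after the data were seen, and the other settings before. Alternatives that need counts (edgeR with other scalings, DESeq2, voom with quality weights, a filter of 50 counts) were not run. Limma called 0 genes under every setting except array weights (4933 genes, 1488 higher and 3445 lower) and leaving out maternal DSS 1. Leaving out each library gave 0 to 12 called genes, 14 to 86 genes with a 2-fold change, 14 to 27 lists, and 401 to 3368 genes with an unadjusted p under 0.05. The 2-fold count of 23 was 35 after TPM scaling, 34 with a pseudocount of 0.1, 127 with array weights and 8 at the stricter filter, which tests fewer genes (8589). Array weights rest on 3 libraries per group, with 5.47 for maternal DSS 2 alone. Other causes were not tested. The 1064 genes with an unadjusted p under 0.05 became 1678 with the replicate block, 3312 with the residual component and 6784 with array weights.

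With the replicate number as a block, limma called 0 genes, 27 had a 2-fold change and 20 lists were called, 19 of them the same. Proximal colon lost its call (adjusted p = 0.05) and MHC class II gained one (0.014, and 0.022 with the sex term). Whether the numbers pair the libraries is not settled. Deviations of same-numbered libraries correlated at 0.28, -0.38 and 0.40, and control 2 and maternal DSS 1 at 0.51, so not every library followed its own number. The 0.40 was the highest value for both control 3 and maternal DSS 3. Deviations from a group mean are tied to one another, so these values cannot exclude a shared litter or batch.

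The 20 called lists fell to 0 with an estimated correlation and to 0 with fry's directional test. Fry's mixed test, which takes changes in either direction together, gave an adjusted p of 0.014 for the glucocorticoid list alone. That value gives no direction for the list. With the length trend removed 16 kept their call and direction, with TPM scaling 17, with median-ratio scaling 18 and with a pseudocount of 0.1 all 20. Array weights ended the calls of heat shock (0.64), xenobiotic (0.38), ketogenesis (0.52), proximal colon (0.14) and stem genes (0.091), and called 7 others: MHC class I (4.1e-05), MHC class II (0.0013), distal colon (0.0016), apoptosis (0.0036), skeletal muscle (0.009), the unfolded protein response (0.016) and enteroendocrine cells (0.033). Among the 43 lists of the main test, the residual component called 4 others, the missing filter 2, the length trend removed 2, the stricter filter 1 and TPM scaling 1. Without a filter 23 of 48 tested lists were called, and after TPM scaling 20 of 47. Lists that the main fit could not test were among them. The stricter filter tested 37 lists and kept 14 of the 20 calls. It ended the calls of the glucocorticoid (0.064), weaning (0.094), proximal colon (0.055), ketogenesis (0.064) and stem (0.13) lists. A further called list had too few genes left to be tested there. The 4 list scores with separate groups became 2 at the stricter filter, 3 with TPM scaling, 5 without a filter and 6 with median-ratio scaling or the length trend removed. Without one library they were 4 to 21, with 21 without maternal DSS 1, 14 without control 3, 9 without maternal DSS 2 and 7 without control 1; fewer libraries come apart more easily. The first component's share of 57.7% was 53.5% without a filter, 61.7% at the stricter filter and 51.7% with the length trend removed.

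No list called in the main test changed direction under any setting; those that did had weak main directions. Their adjusted p were, without a filter, 0.91 for distal colon and 0.99 for interferon; with the block 0.66 for cytokines; with median-ratio scaling 0.87 for distal colon; with TPM scaling 0.49 for the unfolded protein response, 0.43 for cytokines and 0.44 for squamous epithelium; at the stricter filter 0.86 for the unfolded protein response; and with the residual component 0.52 for cytokines. With array weights they were 0.64 for endothelium, 0.78 for goblet cells, 0.097 for cytokines, 0.29 for proliferation, 0.009 for skeletal muscle and 0.98 for tight junctions. With the length trend removed they were 0.52 for distal colon, 0.92 for enteroendocrine cells, 0.90 for the unfolded protein response and 0.95 for skeletal muscle. With fry they were 0.91 for distal colon, 0.85 for the unfolded protein response, 0.91 for interferon, 0.91 for NRF2, 1 for proliferation and 0.91 for tuft cells. Among named genes the log2 fold change became -0.08 for Pparg, -0.02 for Acads, 0.38 for Lcn2 and 0.35 for Hoxb13 with array weights, -0.03 for Echs1 with TPM scaling and 0.03 for Lgr5 with the length trend removed. The cause was not tested.

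Leaving out each library turned other lists that the main test had not called, and 2 of these were called in both directions. Skeletal muscle was called lower without maternal DSS 1 (adjusted p = 0.0041) and higher without maternal DSS 2 (0.018), and squamous epithelium lower without maternal DSS 1 (0.00029) and higher without maternal DSS 3 (0.0059). Distal colon (0.0056) and interferon (0.036) were called higher without maternal DSS 1. Over both directions the adjusted p ranged from 0.0056 to 0.94 for distal colon, 0.0092 to 0.97 for endothelium, 0.0063 to 0.98 for enteroendocrine cells, 0.088 to 0.95 for the unfolded protein response, 0.077 to 0.93 for goblet cells, 0.15 to 0.99 for cytokines, 0.036 to 0.96 for interferon, 0.12 to 0.88 for NRF2, 0.051 to 0.78 for proliferation, 0.0041 to 0.84 for skeletal muscle, 0.00029 to 0.93 for squamous epithelium, 0.25 to 0.93 for tight junctions and 0.17 to 0.97 for tuft cells. The log2 fold change ranged from -0.40 to 0.08 for Muc2, -0.16 to 0.02 for Ocln, -0.22 to 0.01 for Lgr5, -0.50 to 0.39 for Lcn2 and -0.36 to 0.24 for Hoxb13.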

Other observations

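The genes in this part were chosen after their values were seen, except those of the fixed lists. Of the tests below, those of the number of lists with separate groups, of the length trend in the library split and of the further small intestine genes were written before their results were seen, and the others after.

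Single libraries had high values of some genes known from other tissues. Maternal DSS 1 had the highest skeletal muscle and squamous list scores (2.42 and 1.36, controls between -1.05 and 0.91 and between -0.14 and 0.11). The muscle actin gene Acta1 had 188 FPKM there against 21.1 to 76.2 elsewhere, the creatine kinase gene Ckm 120 against 19.1 to 48.9, and the keratin genes Krt5 39.7 against 1.59 to 11.7 and Krt14 38.7 against 2.37 to 16.5. The liver product Alb had 8.23 FPKM in control 1 and at most 1.26 elsewhere, and Serpina1a 0.573 against at most 0.168. Other liver genes did not follow Alb. Cyp2e1 was lowest in control 1 (1.29 against 1.76 to 4.63), and Apoa2 had 0.881 there against 1.45 in maternal DSS 2. Ttr, Cps1, Tat and Hp lay within the range of the other libraries, so Alb does not show liver RNA in control 1.

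Several genes took 1 of 2 levels in the libraries. Tmem254a had 41.9, 45.1 and 41.9 FPKM in control 3, maternal DSS 2 and maternal DSS 3 against 14.7 to 16.1 in the other 3, and Plac9a had 47.6, 42.6 and 38 against 10.2 to 11.6. Both lie on chromosome 14 (25923298 to 25927672 and 25888403 to 25902893 in mm10) beside near-identical copies, so reads may be shared among them (not tested), while their neighbour Anxa11 had 45.8 to 56.1 in all 6 libraries. Ifrd1 on chromosome 12 had 25.8 to 27.5 against 64.4 to 71.3 the other way, and the surface antigen gene Ly6a 117 to 137 against 55.4 to 60.6. H2-Aa had 61.8 to 66 against 37.7 to 41.7 and Saa1 657 to 740 against 242 to 351, while the acute phase gene Lcn2 had 6.75 in control 3 and 1.25 to 2.87 in the other 5. Removing the length trend left 555 genes called between these sets of libraries.

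That split of the libraries may have several sources. Of the 10 splits of the 6 libraries into 3 against 3, all 10 gave at least the real count of 0 called genes, and the highest other count was 2033, from this split, which points to a structure of the libraries. The real split had 23 genes with a 2-fold change (4 of 10 splits gave as many, the highest other 133), 20 called lists (4 of 10, highest other 25) and 4 lists with separate groups (3 of 10, highest other 24). Each other split also called between 10 and 25 lists, so calls with the preset correlation are not particular to the groups. With 10 splits no share can fall under 0.1, so these counts cannot test chance. Sex cannot account for maternal DSS 3, a male library with the highest first component score (26.7). For control 3 and maternal DSS 2, both female with scores of at least 7.5, sex and the other source cannot be told apart because a male library stands with them. A trend with transcript length is not the whole of it, since without the trend the split still called 555 genes where the highest other split called 0. Litter, dam, batch and RNA quality stay open, as the labels name none.

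RNA from kidney is a candidate source of Kap, Spp1 and Fxyd2 in control 3. Kap, a kidney androgen-regulated gene, had 96.1 FPKM there, 17.7 in maternal DSS 2, 12.6 in maternal DSS 3 and at most 0.617 elsewhere. Spp1 had 79.7, 12.4 and 10.3 against at most 0.539, and the ratio of Kap to Spp1 was 1.21, 1.42 and 1.23 in these 3 libraries. That ratio was 1.15 in maternal DSS 1 and 0.527 and 0.627 in controls 1 and 2, where both genes were near the floor. Over 17 other kidney genes, of a list of 32 written before their values were looked at except that of Spink1, the median log2 ratio of control 3 to controls 1 and 2 was 1.47, where 2.5% of random lists of equal level exceeded 0.12. Slc34a1 had 2.77 against 0.0908 and 0.155 and Gpx3 112 against 31.8 and 41.2, while Aqp1 and Pax8 hardly differed and 9 of the 17 are at an FPKM of 1 or more in both other controls. A uterus and placenta list (9 genes) had 0.68 against 0.28 for the same share of random lists and a liver list (8 genes) 0.20 against 0.13, so the test is not specific to kidney, and mixing of RNA between libraries was not tested.

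Small-intestinal and IgA transcripts in maternal DSS 2 and 3 may come from small-intestinal tissue in these libraries. In the list that showed the pattern, 10 of 13 genes were higher in both than in each of the other 4 libraries. Of 17 further small intestine genes with a mean of 0.1 to 10 FPKM, listed after the pattern but before their own values were seen, 11 were (64.7%), against 6.72% of all genes at that level, among them Slc6a19 (3.1 and 2.76 against 0.618 to 0.815) and Npc1l1 (2.12 and 2.14 against 0.659 to 0.856). Ace, Mme, Abcg8, Otc, Khk and Creb3l3 were not, and of the 13 listed genes above that level 5 were. Fabp6, the ileal bile acid binder, had 72.7 and 52.4 FPKM against 1.84 to 14.2, and Apoa1 30.6 and 47.5 against 0.646 to 6.33, but Rbp2 and Slc5a1 were only 1.21 and 1.1 times the control mean and Alpi 0.822 times. Lymphoid follicles cannot be told apart from it: 6 follicular B cell genes had a median log2 ratio to controls of -0.21 (SE 0.20), but 5 of them were under 1 FPKM in every library and they went both ways (Ms4a1 0.33, Fcer2a -0.84). A difference in gut position or in IgA plasma cells after maternal DSS stays open and was not tested. In maternal DSS 1, Igha (51.2) and Igkc (87.1) lay above all controls by less than in the other 2. Derl3 (1.06) and Prdm1 (2.42) also lay above all controls there. Jchain (6.88), Mzb1 (0.433), Tnfrsf17 (0.0874) and Pou2af1 (0.494) lay within the range of the controls.

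A glucocorticoid response in the maternal DSS offspring is a hypothesis for Fkbp5, Zbtb16, Mt1 and Mt2, the 4 genes higher in all 3 of their libraries. A trend with transcript length is argued against as the whole source, since removing it changed their log2 fold changes little. With it removed they were 0.99, 1.40, 0.63 and 0.84 (SE 0.20, 0.27, 0.13 and 0.25), against 0.92, 1.29, 0.70 and 0.94 before. The lowest 2 SE limit was 0.34, but the genes were picked for small p, which largely fixed a limit above 0. The split of the libraries was not tested as a source, because genes picked for keeping the groups apart cut across it. Time of day at collection cannot be told apart: 6 clock genes of one phase minus 3 of the other differed by 0.16 (SE 0.22) between groups, and that interval of -0.28 to 0.61 leaves room for a shift. Of other targets of the receptor, Klf9 had a log2 fold change of 0.15 (SE 0.09), and 0.24 (SE 0.10) with the trend removed, while Tsc22d3, Sgk1, Per1 and Dusp1 had 0.09, -0.10, -0.01 and -0.07. Of the 13 tested genes of the glucocorticoid list, 1 was lower in all 3 maternal DSS libraries than in all controls. Stress at collection or weaning was not tested.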
